A study of Mus musculus with 12 samples.

How the data were processed

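Total RNA from mouse hippocampi was measured on 12 Affymetrix MG-U74A arrays, 3 for each of 4 groups formed by genotype (control or mutant) and treatment (saline or kainate). Each array carried RNA pooled from 3 animals, so each group rests on 9 animals and the unit of replication is the pool. The mutants had lost CREB and CREM per the series title, and the labels do not say how the genes were disrupted. The deposited values are on the log2 scale and were made by the authors with GCRMA in R 2.4.1, a method that subtracts background by probe sequence, normalises quantiles across arrays and summarises each probe set. The table ran from -0.78 to 14.35, and the array medians lay close together, as log2 values do. The version of GCRMA, and whether all arrays were processed together, are not stated. The number of arrays limits the precision, since arrays give no counts.

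The table held 12488 probe sets, of which 66 control probe sets were left out and 12422 were tested, with no filter on level. Symbols came from the platform annotation: 10833 probe sets carried 1 gene symbol, 396 carried several and 1193 none, for 8251 genes. Symbols were checked against the RefSeq annotation of GRCm38.p6 by Entrez identifier, where 10817 matched and 16 had no entry. That annotation gave chromosomes and gene order, and no coordinates are given here. Probe sets with several symbols or none were counted, and appear by name only where stated.

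Groups were compared with limma 3.58.1 in R 4.3.3. A linear model with 1 mean per group was fitted to all 12 arrays, so that the 4 groups share an estimate of the spread (8 residual and 2.48 prior degrees of freedom). Tests were two-sided, and p values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. The contrasts were the kainate effect in controls, the kainate effect in mutants, the difference between these (the interaction), the genotype effect under saline, the genotype effect under kainate, and the genotype effect averaged over treatments. Positive genotype effects mean higher in mutants. Errors of log2 fold changes are standard errors (SE) of the fit with 3 arrays per group. Named genes had 1 symbol, passed the threshold, and had all arrays of the higher group above all arrays of the lower group, a separation that chance gives with a share of 0.1 for 3 arrays against 3. Where several probe sets of a gene passed, the one with the highest mean was named, so a brighter one that did not pass could be left aside. Up to 15 rises and 10 falls were named per comparison, and up to 5 genes with the smallest p where none passed. Creb1 and Crem were always reported.

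Lists of 378 genes in 22 groups were taken from textbook knowledge: activity-regulated immediate early genes, activity-regulated effector genes, known CREB target genes, the CREB and ATF family with coactivators, MAP kinase feedback inhibitors, circadian clock genes, cholesterol synthesis and uptake, cholesterol efflux and turnover, heat shock and unfolded protein response, reactive glia and inflammation, and markers of astrocytes, oligodendrocytes, microglia, endothelium and blood, choroid plexus, general neurons, interneurons, dentate granule neurons, CA1 pyramidal neurons, CA3 and CA2 pyramidal neurons, striatum and thalamus (neighbouring tissue), and sex-linked genes. Each gene was represented by the probe set with the highest mean. Lists were tested with camera from limma (preset correlation 0.01, then an estimated correlation with statmod 1.5.0) and with fry, and adjusted over the lists of a contrast. Camera compares a list with all other genes, while fry asks whether its genes move on balance 1 way or, in its mixed form, in either direction. Per-array list scores (mean log2 value) were compared by exact permutation tests, within treatment for the averaged genotype effect. With 3 arrays against 3 the smallest exact p is 0.1, so such a comparison could not pass 0.05. A further 9 lists were chosen after seeing the data: lysosomal proteins, antigen processing and presentation, interferon response, glutamate receptors, GABA-A receptors, voltage-gated potassium channels, NF-kappa B feedback genes, growth arrest and apoptosis, and histones.

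The groups, contrasts, tests, naming rule, 22 lists and the following alternatives were set before the data were examined: the replicate number as a block, quantile normalisation of the deposited values, centring each array on its median, only probe sets above the median level, an intensity trend with a robust prior, only the arrays compared, probe sets averaged per gene, limma array weights, a fold change of at least 1.5, and leaving out each array in turn. A further 3 alternatives were chosen after seeing the data: replicate 1 against replicates 2 and 3 as a batch block, only the arrays of replicates 2 and 3, and that block without the control kainate replicate 3 array. Whether the replicate numbers pair arrays was read from the correlation of deviations from the group means, since the labels do not say what a number marks. Same-numbered arrays correlated above 0.1 in 3 of 3 cases for control and mutant saline (0.583 to 0.848), for control and mutant kainate (0.315 to 0.745) and for mutant saline and kainate (0.408 to 0.625), but in 2 of 3 for control saline and kainate (lowest -0.0109). Array weights used the gene-by-gene method, since the default method did not converge, and ran from 0.0321 to 6.17.

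The fit was tested on simulated data, in which 200 of 12422 probe sets were changed. Changes of 1 on the log2 scale were recovered in 75% of cases for the kainate effect in controls, 88% in mutants, 62% for the interaction, 84% and 85% for genotype under saline and kainate, and 95% for the averaged genotype effect. Changes of 2 were recovered in 92% to 100% of cases, with 5 to 16 false calls per comparison. A list shifted by 0.5 was called with an estimated median of 0.47, and 0 other lists were called by camera. The simulated noise was independent between genes and held no replicate 1 batch and no compressed array. It therefore does not check the preset correlation of camera, nor the false calls of the real arrays. The contrasts of 3 arrays against 3 had the same design there, so their recovery rates differ only by the draw. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.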

Results

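Expression of 12422 probe sets was measured in hippocampi of control mice and of mutants that had lost the transcription factors CREB and CREM, which act on genes with cAMP response elements. Littermate males and females of 5 to 6 weeks received an intraperitoneal injection of kainate (20 mg/kg), a glutamate receptor agonist that evokes seizures, or of saline, and tissue was taken after 1 hour. Each of the 4 groups had 3 arrays, and each array a pool of 3 animals. The arrays were alike, with correlations across probe sets between 0.973 and 0.998. The replicate 1 arrays of all 4 groups stood apart together: their deviations from the group means correlated at 0.368 to 0.848 with each other and at -0.722 to -0.00779 with those of replicates 2 and 3. The first component of the within-group variance, 47.9% of it, separated them. The control kainate replicate 3 array had an interquartile range of 3.74, against 4.40 to 4.61 on the other 11 arrays.

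The targeted genes were read first. The 3 Creb1 probe sets had control saline levels of 2.93, 3.18 and 3.89, and their mean levels lay at percentiles 26.0, 32.2 and 45.0 of the array. Their averaged differences between mutants and controls were -0.09 (SE 0.07), -0.12 (SE 0.10) and -0.11 (SE 0.08), each with adjusted p = 0.63. The brighter of the Crem probe sets (percentile 50.5) stood at 4.34 ± 0.10 (SD, n = 3) in control saline, 4.70 ± 0.17 in control kainate and 4.27 ± 0.06 in mutant saline arrays. Its genotype difference was -0.51 under kainate (SE 0.10, adjusted p = 0.0889) and -0.29 averaged (SE 0.07, adjusted p = 0.141). Without the control kainate replicate 1 array these became -0.60 (adjusted p = 0.042) and -0.34 (adjusted p = 0.0465), and over all alternatives the adjusted p ran from 0.042 to 0.702 and from 0.0259 to 0.381. The dimmer Crem probe set (percentile 22.4) differed by -0.25 averaged (SE 0.07, adjusted p = 0.286). Over its alternatives the adjusted p ran from 0.0304 to 0.765 averaged and from 0.0322 to 1 under saline, and it passed in both with array weights. Where these probe sets lie relative to the disrupted parts is not known, so the values do not test the loss of either protein.

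The kainate effect in control mice asks which genes responded within 1 hour when CREB and CREM were present. Immediate early transcription factors and signalling genes rose steeply. Ier2, an early response gene, rose 91.2-fold (log2 6.51, SE 0.18, n = 3), and the AP-1 components Fosb and Fos rose 59.2-fold (log2 5.89, SE 0.39) and 27.3-fold (log2 4.77, SE 0.13). The antiproliferative gene Btg2 rose by 5.36 (SE 0.12), the growth arrest gene Gadd45g by 5.00 (SE 0.67), and the zinc finger factor Egr2 by 4.75 (SE 0.17). Atf3, a stress-induced factor of the ATF family, rose by 4.61 (SE 0.29), and Ptgs2, the inducible cyclooxygenase, by 4.08 (SE 0.30). Further rises were those of Dusp1 (3.50), Nr4a1 (3.33), Rgs2 (3.23), Junb (3.21), Ccn1 (2.78), Nfil3 (2.52) and Ppp1r15a (2.43). Falls were small: Pkia, an inhibitor of protein kinase A, fell by 0.77 (SE 0.13), Nfib by 0.76, Rsrp1 by 0.73, Tef by 0.71 and Cdkn2d by 0.52. The brighter Nfib probe set (percentile 95.3) stood at -0.29 and did not pass (adjusted p = 0.694).

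Among the lists in controls, 21 of 36 immediate early genes rose, 0 fell and 15 did not pass (median 1.68, camera adjusted p = 5.42e-73, and adjusted p = 4.02e-05 with an estimated correlation). Adjusted over the list alone, 29 rose and 1 fell. Of 37 known CREB target genes, 13 rose and 24 did not pass, and 18 rose adjusted over the list alone (median 0.22, adjusted p = 1.49e-28, and adjusted p = 2.25e-05 with an estimated correlation). These lists share 14 measured genes. Of 7 MAP kinase feedback inhibitors, Dusp1, Errfi1 (2.17, SE 0.10) and Dusp6 (1.28, SE 0.13) rose, also when adjusted over the list alone (adjusted p = 2.88e-07, and adjusted p = 0.00348 with an estimated correlation). Of 23 activity-regulated effector genes, Gem (1.26, SE 0.22), a small GTP-binding protein, and Scg2 (0.57, SE 0.10), a secretory granule protein, rose, and 5 rose adjusted over the list alone (adjusted p = 0.00159, and adjusted p = 0.0216 with an estimated correlation). That list lost its call without control kainate replicate 2 (adjusted p = 0.0809, and 6.6e-06 to 0.0809 over its alternatives). Camera did not call the other 18 lists, with adjusted p between 0.0531 for reactive glia and 0.862 for dentate granule neurons. Among 16 clock genes Nfil3 rose and Tef fell, and fry's mixed test called that list (adjusted p = 4.21e-08).

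In limma, 41 probe sets passed for kainate in controls, 35 higher and 6 lower, of 915 with unadjusted p under 0.05 (621 by chance). The count was 27 without control saline replicate 2, 22 with only the arrays compared, and 146 (46 higher, 100 lower) with replicates 2 and 3 only. Centring arrays on their medians gave 28 higher and 0 lower, against which the falls are to be read. The 15 named rises kept their calls with each array left out, and all but Ppp1r15a did so in every alternative run. With each array left out, each of the 5 named falls lost its call at least 3 times. The highest adjusted p among these fits was 0.221 for Pkia (control saline replicate 2), 0.155 for Nfib, 0.198 for Rsrp1 and 0.11 for Cdkn2d (control saline replicate 3), and 0.0841 for Tef (control saline replicate 2). Over all alternatives it was 0.548 for Pkia, 0.534 for Nfib, 0.204 for Rsrp1, 0.372 for Tef and 0.539 for Cdkn2d.

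The same question was asked in the mutants. Fos rose 60.4-fold (log2 5.92, SE 0.13, n = 3), Fosb 52.6-fold (log2 5.72, SE 0.39) and Ier2 43.1-fold (log2 5.43, SE 0.18). Egr2 rose by 4.76 (SE 0.17), Btg2 by 4.64 (SE 0.12), Gadd45g by 4.56 (SE 0.67) and Ptgs2 by 4.42 (SE 0.30). The orphan nuclear receptor Nr4a1 rose by 4.09 (SE 0.16), and Nfkbiz, a regulator of NF-kappa B, by 3.93 (SE 0.54). Dusp1 (3.65), Junb (3.02), Atf3 (2.82), Ccn1 (2.72), Rgs2 (2.57) and Klf4 (2.10) also rose. Adam28 fell by 0.83 (SE 0.14), Sf1 by 0.69, Tef by 0.60 and Cdkn2d by 0.47.

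In the mutants, 20 of 36 immediate early genes rose and 16 did not pass, with 29 rising adjusted over the list alone (median 1.52, adjusted p = 2.3e-90, and adjusted p = 1.74e-05 with an estimated correlation). Of the 37 CREB target genes 12 rose, and 17 adjusted over the list alone (median 0.35, adjusted p = 1.41e-35, and adjusted p = 9.39e-06 with an estimated correlation). Dusp1, Errfi1 (1.89, SE 0.10) and Dusp6 (1.24, SE 0.13) rose among 7 MAP kinase feedback inhibitors, also adjusted over the list alone (adjusted p = 1.27e-11, and adjusted p = 0.000631 with an estimated correlation). Of 23 effector genes Gem (1.79, SE 0.22) and Sgk1 (0.65, SE 0.10), a kinase, rose, and 5 adjusted over the list alone (adjusted p = 7.48e-07, and adjusted p = 0.00217 with an estimated correlation). None of the 9 endothelium and blood markers passed in limma, and 2 were higher adjusted over the list alone, while the list was higher as a whole (median 0.26, adjusted p = 7.63e-05, and adjusted p = 0.0158 with an estimated correlation). Its highest member was the haemoglobin gene Hba-a1, at 0.77 (SE 0.14, adjusted p = 0.0642).

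The calls of 3 more lists in the mutants, each with 0 members past the threshold in limma, were lost with an estimated correlation. Reactive glia (median 0.11, adjusted p = 0.00112) had an adjusted p = 0.393 with an estimated correlation, and 2 members were higher adjusted over the list alone. Microglia (median 0.20, adjusted p = 0.0417) had an adjusted p = 0.393 with an estimated correlation and 0 such members. Heat shock (median 0.15, adjusted p = 0.0326) had an adjusted p = 0.284 with an estimated correlation and 1 such member. Leaving out an array also ended these calls: for reactive glia mutant kainate replicate 3 (adjusted p = 0.0822), for heat shock mutant saline replicate 1 (0.118) and mutant kainate replicate 2 (0.125), and for microglia control kainate replicate 3, mutant saline replicate 1, mutant saline replicate 3 and mutant kainate replicate 3 (0.0552 to 0.401). Camera did not call the other 14 lists, while fry's mixed test called clock genes (adjusted p = 3.9e-05), of which Tef fell.

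In limma, 37 probe sets passed for kainate in mutants, 33 higher and 4 lower, of 780 with unadjusted p under 0.05 (621 by chance). Modelling replicate 1 as a batch gave 64 (48 higher, 16 lower), and replicates 2 and 3 alone gave 94 (43 higher, 51 lower). With each array left out, 12 of the 19 named genes kept their calls. Among these fits the highest adjusted p was 0.101 for Gadd45g, 0.0732 for Nfkbiz and 0.0941 for Klf4 (mutant kainate replicate 2), 0.222 for Adam28 and 0.216 for Tef (mutant saline replicate 3), and 0.144 for Sf1 and 0.211 for Cdkn2d (mutant saline replicate 2). The replicate block ended the calls of Tef (adjusted p = 0.0609, and 0.000682 to 0.23 over its alternatives) and Cdkn2d (adjusted p = 0.0603, and 1.92e-05 to 0.245 over its alternatives).

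**Figure D1:**
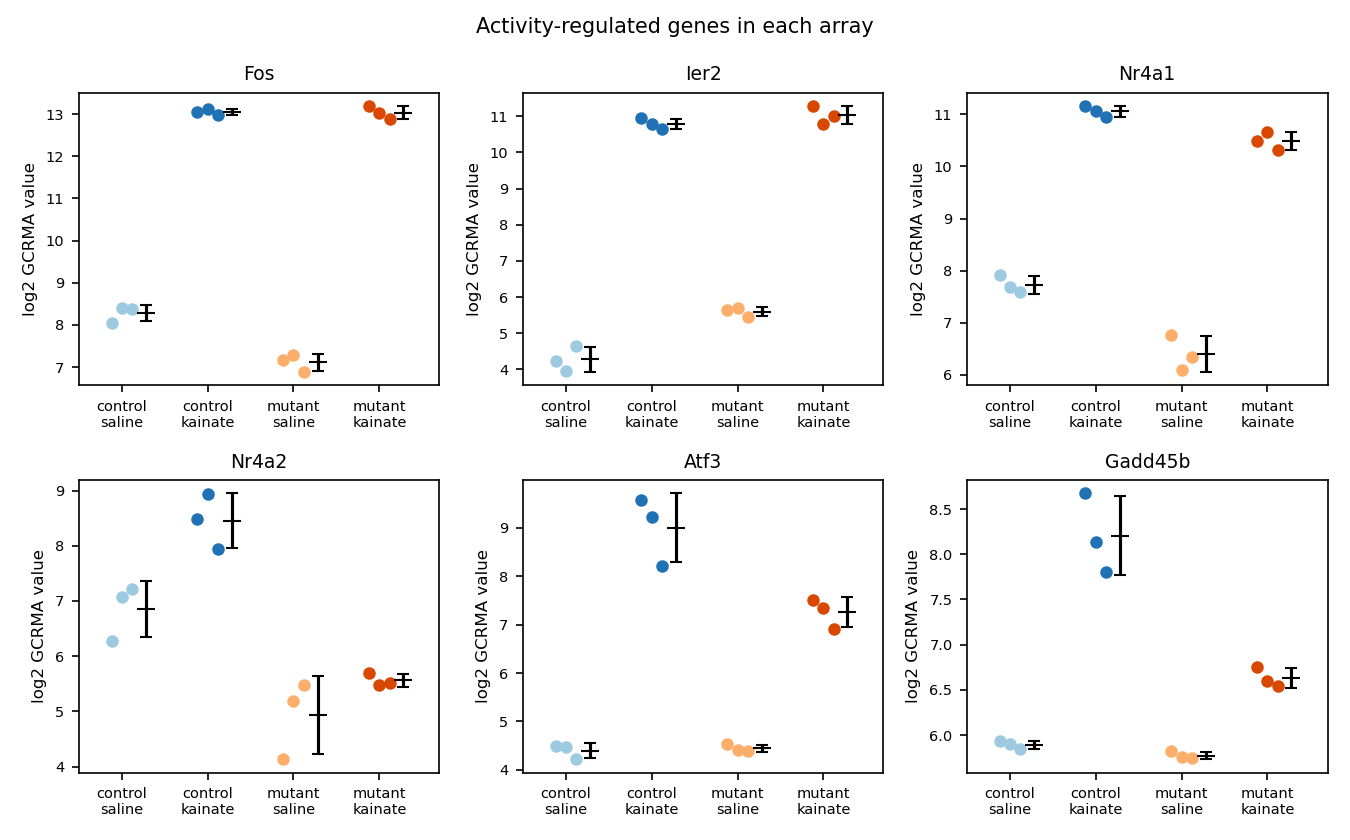
Levels of 6 activity-regulated genes (y axis, log2 GCRMA value) in each array of the 4 groups (x axis), with bars for the mean ± SD of 3 arrays. After kainate Fos lay at 13.05 in controls and 13.03 in mutants, Gadd45b at 8.21 and 6.63, and Nr4a2 at 8.45 and 5.56.

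Whether loss of CREB and CREM altered the kainate response was asked by the interaction. No gene passed in limma, where 0 of 12422 probe sets were called and 107 had an unadjusted p under 0.05, fewer than the 621 expected by chance. With each array left out that number ran from 61 (control saline replicate 2) to 423 (control kainate replicate 2). The shortfall is therefore no evidence that the responses were equal. The smallest p values belonged to genes induced by activity. The kainate response was larger in mutants for Fos, by 1.14 (SE 0.19, adjusted p = 0.333), and for Rasl11b, a Ras-like protein, by 0.71 (SE 0.12, adjusted p = 0.333). It was smaller for Gadd45b, by -1.46 (SE 0.24, adjusted p = 0.333), for the middle one of 3 Atf3 probe sets by level (percentile 49.8), by -1.67 (SE 0.24, adjusted p = 0.333), and for Btg2, by -0.72 (SE 0.17, adjusted p = 0.939). The brightest Atf3 probe set differed by -1.80 (adjusted p = 0.939), and the dimmest, at percentile 0.531, by -0.03 (adjusted p = 0.948). Adjusted over the immediate early list alone, the differences of Fos and Nr4a1 (0.76) were positive and those of Gadd45b, Atf3, Ier2 (-1.08), Btg2 and Nfil3 (-1.48) negative, 2 higher and 5 lower of 36. Those of Fos and Ier2 came from the saline level. Their genotype differences were -1.16 and 1.32 under saline, and -0.02 and 0.23 under kainate. For Nr4a1 these were -1.33 and -0.57. Adjusted over the CREB target list alone, Fos was higher and Gadd45b, Btg2 and Atf3 were lower.

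Neither list moved as a whole in the interaction (immediate early median -0.07, adjusted p = 0.377, and CREB targets -0.04, adjusted p = 0.732), while fry's mixed test, which takes changes in either direction, gave adjusted p = 0.000209 and 8.82e-06. Heat shock genes were the called list, with a median of 0.22, 11 of 13 genes positive and 0 past the threshold in limma, overall or adjusted over the list alone (adjusted p = 0.0165). It had an adjusted p = 0.629 with an estimated correlation. It was also lost without control saline replicate 2, control kainate replicate 1, control kainate replicate 3 or mutant saline replicate 1 (0.0652 to 0.331). Exact permutation tests of the 22 list scores gave an adjusted p of 0.995 each.

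The count of the interaction rested on the control kainate replicate 3 array. Without it, 5 probe sets passed, all with adjusted p = 0.0248: the brightest Atf3 probe set (-2.19, SE 0.24), the middle one (-1.83, SE 0.20), Gadd45b (-1.66, SE 0.18), Gpr19 (-0.97, SE 0.11), an orphan receptor, and an unnamed probe set (-0.94, SE 0.09). Over all alternatives the adjusted p of the middle Atf3 probe set ran from 0.00314 to 0.999, and that of Gadd45b from 0.00297 to 0.999. Array weights gave 8 probe sets, and the replicate 1 batch block without that array gave 6, with Siah2 (-1.47, SE 0.12), a ubiquitin ligase, as a further gene. Within replicates 2 and 3, and with the replicate 1 block alone, the count was 0 in limma (298 and 182 at unadjusted p under 0.05).

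Most probe sets called for kainate in controls moved in the same direction in mutants. Equal responses are not shown by this, since fry's mixed test called the immediate early list in the interaction. Of 35 probe sets higher after kainate in controls, 24 were among the 33 higher in mutants (0.093 expected by independence), and 34 had the same sign there. Of the 6 lower in controls 2 were among the 4 lower in mutants. Pearson's r of the log2 changes was 0.683 over all probe sets and 0.945 over the 36 immediate early genes. Genes are not independent replicates. The slope over that list was 0.912 for mutants on controls and 0.98 for controls on mutants.

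**Figure D2:**
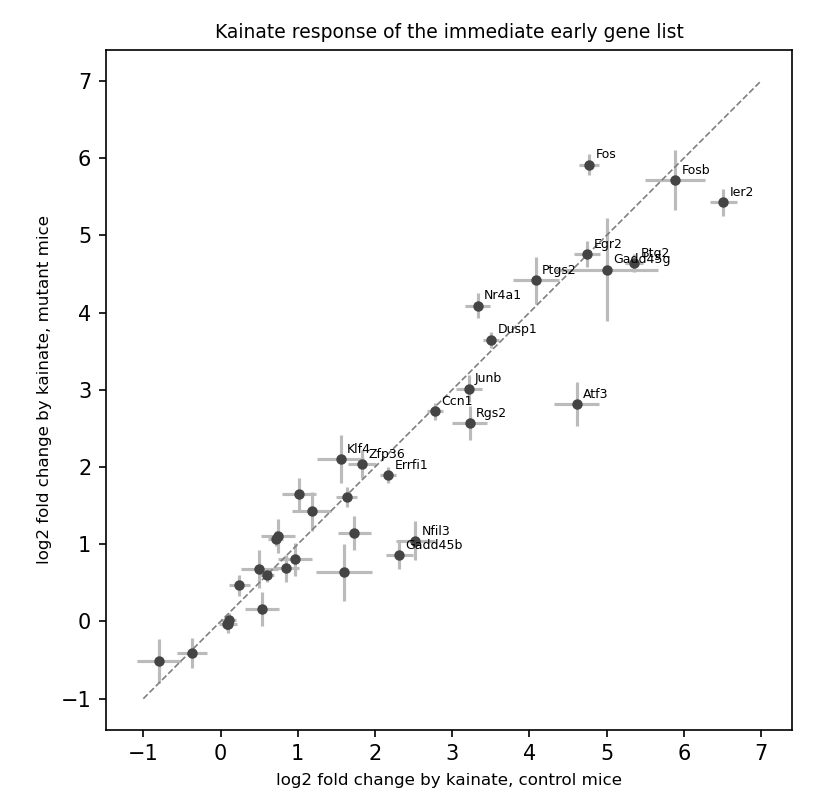
Log2 fold change by kainate in mutants (y axis) against controls (x axis) for the 36 immediate early genes, with SE bars and a dashed line of equal response. Ier2, at 6.51 and 5.43, and Atf3, at 4.61 and 2.82, lie below the line, and Fos, at 4.77 and 5.92, lies above it. Under saline the mutants differed by 1.32 for Ier2 and -1.16 for Fos, and under kainate by 0.23 and -0.02.

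The averaged genotype effect takes the mean of the genotype differences under saline and under kainate. Several genes of microglia, complement and reactive astrocytes were higher in the mutants. Cd52, a surface protein of leukocytes, rose 5.00-fold (log2 2.32, SE 0.19, 6 against 6 arrays), the chemokine Ccl9 rose by 2.16 (SE 0.38), and Tyrobp, a signalling adaptor of microglia, rose by 1.76 (SE 0.12). Gfap, the filament protein of reactive astrocytes, rose by 1.62 (SE 0.21), and Mpeg1, a macrophage gene, by 1.43 (SE 0.10). The dimmer Mpeg1 probe set (percentile 48.7) stood at -0.13 averaged and did not pass (adjusted p = 0.633). It stood at 0.01 under saline and -0.27 under kainate. Lysozyme Lyz2 rose by 1.41, C1qc, C1qb and C1qa, the subunits of complement C1q, by 1.24, 1.17 and 1.08, the immunoproteasome subunit Psmb8 by 1.31, the class II invariant chain Cd74 by 1.11 and the oncostatin M receptor Osmr by 1.06. The histone gene H1f2 had the smallest p of all, rising by 1.28 (SE 0.05, adjusted p = 1.29e-06). Coq7, an enzyme of ubiquinone synthesis, and Man2b1, a lysosomal mannosidase, rose by 1.03 and 0.99.

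Among transcription factor genes Nr4a2 fell by 2.41 (SE 0.26, adjusted p = 0.00208) and Nr4a1 by 0.95 (SE 0.12, adjusted p = 0.00402). Wfs1, a marker of CA1 pyramidal neurons, fell by 1.04 (SE 0.14), Lefty1 by 0.99 (SE 0.17), Rmdn3 by 0.93 (SE 0.10), Rtl6 by 0.92 (SE 0.12), the kinase gene Stk16 by 0.90 (SE 0.10), Gadd45b by 0.85 (SE 0.12), Mrm3 by 0.72 (SE 0.13) and Imp3 by 0.64 (SE 0.08). The average of Gadd45b came from -0.12 under saline (adjusted p = 1) and -1.58 under kainate, and its difference in response did not pass (adjusted p = 0.333).

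Microglial markers were the group with the smallest p: 7 of 13 rose, 0 fell and 6 did not pass, with 8 rising adjusted over the list alone (median 0.82, adjusted p = 5.99e-19, and adjusted p = 0.00579 with an estimated correlation). Beyond those named, Ctss (0.91), Laptm5 (0.82) and Csf1r (0.70) rose. Of 30 reactive glia genes 10 rose, among them Cd14 (0.90) and Ctsd (0.68), and 15 adjusted over the list alone (median 0.34, adjusted p = 1.42e-17, and adjusted p = 0.0146 with an estimated correlation). These lists share 6 measured genes. Of 13 astrocyte markers Gfap rose, also adjusted over the list alone (median 0.15, adjusted p = 0.000141, and adjusted p = 0.0109 with an estimated correlation). Endothelium and blood markers were called (median 0.14, adjusted p = 0.0332) with 0 of 9 past the threshold in limma, overall or adjusted over the list alone, and had an adjusted p = 0.131 with an estimated correlation. Oligodendrocyte markers had a median of -0.07 (adjusted p = 0.298).

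The cholesterol lists moved apart. Of 17 genes of synthesis and uptake Cyp51, a demethylase of the sterol pathway, fell by 0.41 (SE 0.06) and 16 did not pass, with 16 of 17 negative and 2 falling adjusted over the list alone (median -0.23, adjusted p = 9.93e-07, and adjusted p = 0.0109 with an estimated correlation). Of 14 genes of efflux and turnover the transporter Abca1 rose by 0.73 (SE 0.13) and 13 did not pass, with 3 rising adjusted over the list alone (median 0.17, adjusted p = 0.000141, and adjusted p = 0.0109 with an estimated correlation). Of 5 CA1 markers Wfs1 fell and 4 did not pass, with 3 falling adjusted over the list alone (median -0.53, adjusted p = 0.000306, and adjusted p = 0.0353 with an estimated correlation).

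Known CREB target genes were lower in the mutants as a list. That list includes Crem, itself a targeted gene, at -0.29 (adjusted p = 0.141). No test of the list without Crem is given here. Of 37 target genes Nr4a2, Nr4a1, Gadd45b and Fos (-0.59, SE 0.09, from -1.16 under saline and -0.02 under kainate) fell, 0 rose and 33 did not pass (median -0.09, adjusted p = 0.000625, and adjusted p = 0.0109 with an estimated correlation). Adjusted over the list alone 9 fell and 2 rose. Of 36 immediate early genes the same 4 fell and Ier2 rose by 0.78 (SE 0.13), while adjusted over the list alone 8 fell and 1 rose (median -0.07, adjusted p = 0.0299). This list had an adjusted p = 0.321 with an estimated correlation. Camera did not call the remaining lists: effector genes (median -0.11, adjusted p = 0.23), the CREB and ATF family (-0.03, 0.368), MAP kinase feedback inhibitors (-0.03, 0.35), clock genes (-0.04, 0.298), heat shock (0.04, 0.11), choroid plexus (0.16, 0.669), general neurons (-0.15, 0.23), interneurons (0.08, 0.316), dentate granule neurons (-0.03, 0.779), CA3 and CA2 neurons (-0.10, 0.892), striatum and thalamus (0.01, 0.995) and sex-linked genes (-0.18, 0.442). Fry called effector genes (adjusted p = 0.0154) and oligodendrocyte markers (adjusted p = 0.0498) as lower, and its mixed test called CA3 and CA2 neurons (adjusted p = 0.000976), of which 1 gene rose. Median, mean and test of camera differed in sign for CA3 and CA2 neurons, striatum and thalamus, and sex-linked genes.

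Array scores were compared by exact permutation within treatment, with p = 0.005 (adjusted 0.022) for microglia, reactive glia, both cholesterol lists and CREB targets, and 0.01 (adjusted 0.0314) for CA1 and for endothelium and blood. Astrocytes (exact p = 0.035, adjusted 0.0856) and immediate early genes (exact p = 0.045, adjusted 0.099), both called by camera, did not pass. Between same-numbered arrays the mutant minus control difference had the same sign in 6 of 6 for both, from 0.17 to 0.34 for astrocytes and from -0.35 to -0.06 for immediate early genes. Endothelium and blood was higher in 5 of 6. Exact sign flips of these differences, a test chosen after the result was seen, gave p = 0.0312 (adjusted 0.0764) for astrocytes, immediate early and effector genes, microglia, reactive glia, both cholesterol lists, CREB targets and CA1, the smallest they can give, and p = 0.0625 (adjusted 0.115) for endothelium and blood. None of the 22 lists passed by sign flips after adjustment. The microglia score was higher by 0.74 in mutants, and each of the 6 mutant arrays (6.67 or more) exceeded each of the 6 control arrays (6.31 or less).

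**Figure D3:**
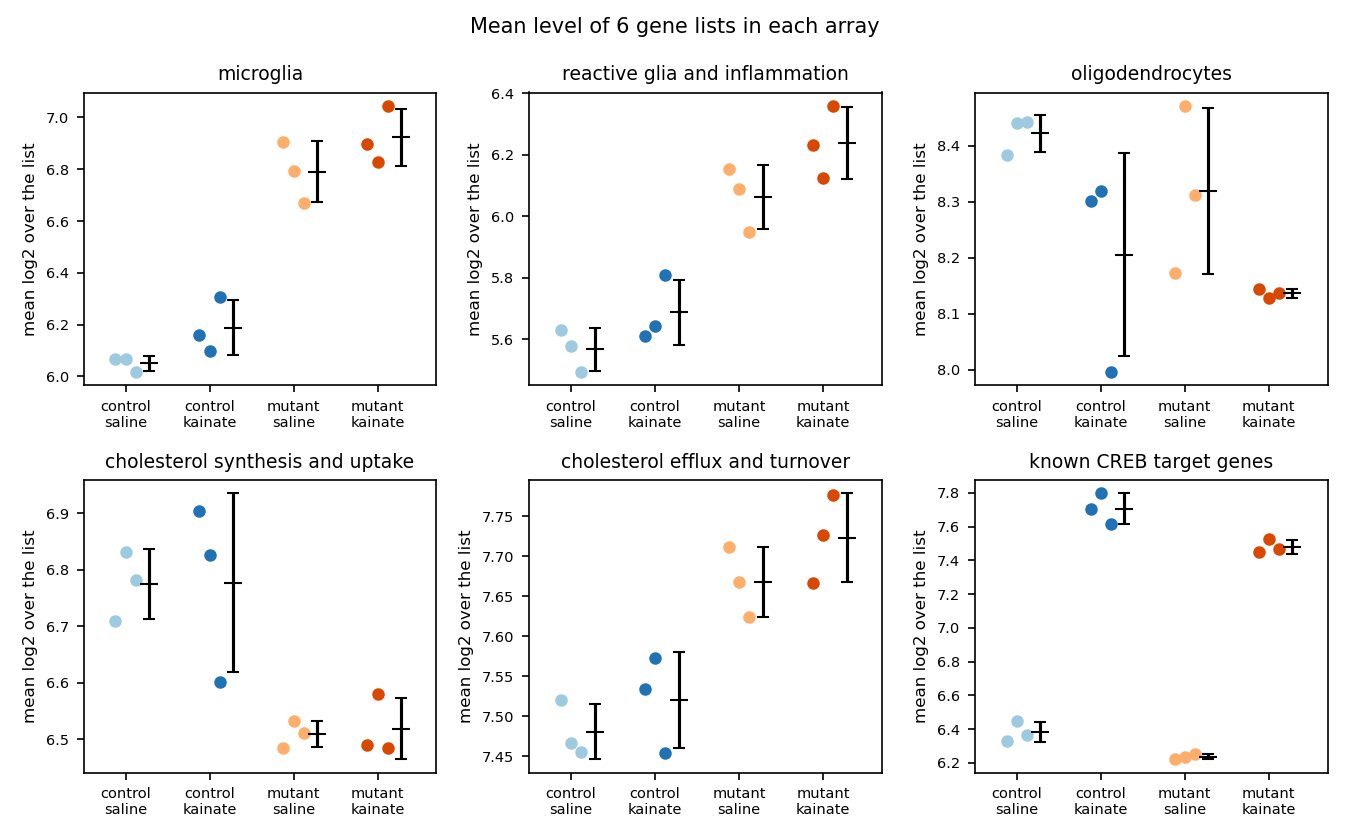
Mean log2 value over the genes of 6 lists (y axis) in each array of the 4 groups (x axis), with bars for the mean ± SD of 3 arrays. The microglia score averaged 6.05 and 6.19 in control saline and control kainate arrays, and 6.79 and 6.92 in mutant saline and mutant kainate arrays.

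In limma, 76 probe sets passed for the averaged genotype effect, 52 higher and 24 lower, of 743 with unadjusted p under 0.05 (621 by chance). Quantile normalisation gave 42 higher and 33 lower, and centring on medians 42 and 9. The count was 45 without control saline replicate 3, 41 without mutant saline replicate 2, 48 without mutant saline replicate 3, 50 without mutant kainate replicate 2 and 43 without mutant kainate replicate 3. It was 124 with the replicate block, 140 with the replicate 1 batch block and 47 with replicates 2 and 3 only. With each array left out, 19 of the 25 named genes kept their calls, and 16 did so in every alternative run. With an array left out, and not over the other alternatives, the highest adjusted p was 0.114 for Ccl9 and 0.0591 for Lyz2 (mutant saline replicate 2), 0.071 for Cd74 and 0.102 for Lefty1 (mutant kainate replicate 3), and 0.109 for Osmr and 0.134 for Mrm3 (control saline replicate 3). The list calls of CREB targets, both cholesterol lists, reactive glia, astrocytes, microglia and CA1 neurons held in every alternative run. Those of immediate early genes (without control saline replicate 3, control kainate replicate 1, control kainate replicate 2, mutant saline replicate 1, mutant kainate replicate 1 or mutant kainate replicate 3, 0.0521 to 0.304) and of endothelium and blood (without control kainate replicate 1, control kainate replicate 2, mutant saline replicate 1 or mutant kainate replicate 2, 0.0623 to 0.146) did not.

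The genotype effect under saline gives the difference at rest. Cd52 rose by 1.82 (SE 0.27, n = 3), Tyrobp by 1.73 (SE 0.17), Mpeg1 by 1.52 (SE 0.14), Psmb8 by 1.35 (SE 0.17), H1f2 by 1.29 (SE 0.07), C1qb by 1.14 (SE 0.13), C1qa by 0.97 (SE 0.14) and Ctss by 0.92 (SE 0.14). Among immediate early genes Ier2 rose by 1.32 (SE 0.18), while Nr4a1 and Fos fell by 1.33 (SE 0.16) and 1.16 (SE 0.13). Rmdn3 fell by 0.97 (SE 0.13) and Imp3 by 0.70 (SE 0.11).

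Under saline 4 of 13 microglial markers rose, and 9 adjusted over the list alone (median 0.75, adjusted p = 1.03e-31, and adjusted p = 0.000924 with an estimated correlation). Of 30 reactive glia genes 4 rose, and 13 adjusted over the list alone (median 0.34, adjusted p = 5.13e-25, and adjusted p = 0.006 with an estimated correlation). Of the 37 CREB targets Fos and Nr4a1 fell, and 4 fell adjusted over the list alone (median -0.04, adjusted p = 0.00135, and adjusted p = 0.0112 with an estimated correlation). That call was lost with the replicate 1 batch block without control kainate replicate 3 (adjusted p = 0.0684, and 0.000384 to 0.0684 over its alternatives). The next lists had 0 members past the threshold in limma and moved as a whole: astrocytes (median 0.16, adjusted p = 9.7e-07, and adjusted p = 0.00566 with an estimated correlation), cholesterol synthesis (-0.28, adjusted p = 2.8e-08, and adjusted p = 0.00566 with an estimated correlation), cholesterol efflux (0.16, adjusted p = 1.86e-05, and adjusted p = 0.006 with an estimated correlation) and CA1 neurons (-0.53, adjusted p = 4.39e-06, and adjusted p = 0.0112 with an estimated correlation). Adjusted over the list alone 1, 2, 0 and 2 of their members passed. Effector genes (median -0.05, adjusted p = 0.0399, 0 of 23 passing in limma and 1 lower adjusted over the list alone) had an adjusted p = 0.0745 with an estimated correlation. That call was lost without control saline replicate 2, control saline replicate 3, control kainate replicate 3, mutant saline replicate 1 or mutant saline replicate 3 (0.0602 to 0.221). Camera did not call the other 14 lists, while fry's mixed test called immediate early genes (adjusted p = 1.39e-06) and CA3 and CA2 neurons (adjusted p = 0.00563).

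In limma, 17 probe sets passed under saline, 13 higher and 4 lower. Those with unadjusted p under 0.05 numbered 319, fewer than the 621 expected by chance. Quantile normalisation gave 7 higher and 6 lower. The count was 10 without control saline replicate 1, 8 without control saline replicate 2, 9 without control saline replicate 3, 8 without mutant saline replicate 2 and 10 without mutant saline replicate 3, 30 with the replicate block and 38 with the replicate 1 batch block. Of the 13 named genes Tyrobp, Mpeg1, H1f2, C1qb and Fos kept their calls with each array left out, and of these H1f2 alone in every alternative. Replicates 2 and 3 ended the calls of the other 4, quantile normalisation and gene averages those of Mpeg1 and C1qb, and only the arrays compared that of Fos. With an array left out, the highest adjusted p was 0.194 for Cd52, 0.193 for C1qa, 0.24 for Ctss and 0.274 for Imp3 (control saline replicate 3), 0.0721 for Psmb8, 0.131 for Ier2 and 0.145 for Rmdn3 (mutant saline replicate 2), and 0.0681 for Nr4a1 (mutant saline replicate 3). Over all alternatives it reached 0.335 for Cd52, 0.27 for Ier2, 0.234 for Psmb8 and 0.0793 for Nr4a1. The replicate block ended the call of Imp3 (adjusted p = 0.0603, and 0.000264 to 0.287 over its alternatives). With replicates 2 and 3 only, 2 probe sets passed.

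The genotype effect under kainate gives the difference 1 hour after the injection. Among the activity-regulated genes Nr4a2 fell by 2.89 (SE 0.36, n = 3), Atf3 by 1.75 (SE 0.29) and Nfil3 by 1.62 (SE 0.25). Gadd45b fell by 1.58 (SE 0.17) and Siah2 fell by 1.45 (SE 0.24). Stk16 fell by 1.06 (SE 0.14), Rmdn3 by 0.88, Gpr19 by 0.81, Pacrgl by 0.70 and D430019H16Rik by 0.60. The glial genes rose here too: Cd52 by 2.82 (SE 0.27), Tyrobp by 1.80 (SE 0.17), Cd74 by 1.46, Mpeg1 by 1.35, C1qc by 1.34, Psmb8 by 1.27, C1qb by 1.21, C1qa by 1.19, Laptm5 by 1.00, Ctss by 0.90 and Ctsd by 0.74. H1f2 rose by 1.27 (SE 0.07), Coq7 by 1.19 (SE 0.17), Man2b1 by 1.11 (SE 0.18) and Tmem176a by 1.05 (SE 0.15). That these differences depended on kainate was not shown, since the interaction called no gene in limma (107 at unadjusted p under 0.05).

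Of 13 microglial markers 6 rose under kainate, and 8 adjusted over the list alone (median 0.90, adjusted p = 8.83e-12, and adjusted p = 0.03 with an estimated correlation). Of 30 reactive glia genes 6 rose, and 13 adjusted over the list alone (median 0.43, adjusted p = 8.83e-12), with an adjusted p = 0.052 with an estimated correlation. Of 36 immediate early genes Nr4a2, Atf3, Nfil3 and Gadd45b fell, and 8 adjusted over the list alone (median -0.12, adjusted p = 0.0323), with an adjusted p = 0.376 with an estimated correlation. Of 37 CREB targets Nr4a2, Atf3 and Gadd45b fell, with 8 lower and 1 higher adjusted over the list alone (median -0.14, adjusted p = 0.0133), and an adjusted p = 0.052 with an estimated correlation. In cholesterol synthesis Cyp51 fell by 0.48 (SE 0.08), also adjusted over the list alone (median -0.27, adjusted p = 0.000803), with an adjusted p = 0.052 with an estimated correlation.

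Another 5 lists were called under kainate with 0 members past the threshold in limma, and lost the call with an estimated correlation. Cholesterol efflux (median 0.19, adjusted p = 0.0126) had an adjusted p = 0.052 with an estimated correlation, and heat shock (0.12, adjusted p = 0.0133) had an adjusted p = 0.125 with an estimated correlation. Astrocytes (0.14, adjusted p = 0.0179) had an adjusted p = 0.0752 with an estimated correlation, endothelium and blood (0.21, adjusted p = 0.0333) had an adjusted p = 0.125 with an estimated correlation, and CA1 neurons (-0.37, adjusted p = 0.0133) had an adjusted p = 0.125 with an estimated correlation. Adjusted over the list alone 1, 0, 1, 0 and 2 of their members passed. Without control kainate replicate 1, adjusted p was 0.0863 for cholesterol synthesis, 0.0704 for cholesterol efflux and CREB targets, 0.108 for heat shock, astrocytes and CA1 neurons, and 0.242 for immediate early genes and endothelium and blood. Without control kainate replicate 2 it was 0.244 for CREB targets, 0.493 for immediate early genes, 0.0976 for astrocytes, and 0.0981 for endothelium and CA1 neurons. Further calls ended without control kainate replicate 3 (heat shock, 0.0691), mutant kainate replicate 1 (immediate early genes, 0.122), mutant kainate replicate 2 (astrocytes 0.0532, endothelium 0.141) and mutant kainate replicate 3 (immediate early genes 0.0868, astrocytes and endothelium 0.0569). Camera did not call the other 12 lists, while fry's mixed test called CA3 and CA2 neurons (adjusted p = 0.0169).

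In limma, 44 probe sets passed under kainate, 27 higher and 17 lower. Those with unadjusted p under 0.05 numbered 616, no more than the 621 expected by chance. Quantile normalisation gave 18 higher and 24 lower, and centring on medians 16 and 4. The count was 28 without control saline replicate 2, 26 without control saline replicate 3, 21 without control kainate replicate 2, 20 without mutant saline replicate 2, 22 without mutant saline replicate 3, 21 without mutant kainate replicate 1, 21 without mutant kainate replicate 2 and 12 without mutant kainate replicate 3. It was 5 with only the arrays compared, 67 with the replicate block, which ended the call of D430019H16Rik (adjusted p = 0.0617, and 0.00661 to 0.537 over its alternatives), 77 with the replicate 1 batch block, and 10 with replicates 2 and 3 only. Of the 25 named genes 9 kept their calls with each array left out: Cd52, Tyrobp, Mpeg1, H1f2, Psmb8, C1qb, C1qa, Laptm5 and Gadd45b, of which H1f2 alone did so in every alternative. Without mutant kainate replicate 3, adjusted p was 0.0623 for Nr4a2, 0.191 for Atf3 and Siah2, 0.209 for Gpr19, 0.0778 for Stk16 and Nfil3, 0.145 for Rmdn3, 0.111 for Pacrgl, 0.23 for D430019H16Rik and Cd74, 0.159 for C1qc, 0.0911 for Coq7, 0.162 for Man2b1, 0.0673 for Tmem176a, 0.141 for Ctss and 0.205 for Ctsd.

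The genotype differences under saline and kainate share no arrays. Of 13 probe sets higher in mutants under saline, 10 were among the 27 higher under kainate (0.0283 expected by independence), and 13 had the same sign there. Of 4 lower under saline 1 was among the 17 lower under kainate.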

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

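The tests of explanations here were chosen after the results they measure had been seen, except the counts over other splits of the arrays without a block. Btg2 was singled out because mutant arrays lay above control arrays after saline and below them after kainate, with a difference in response of -0.72 (SE 0.17), which did not pass (adjusted p = 0.939, and 0.127 to 1 over the alternatives). Rasl11b moved the other way in the same manner, with a difference of 0.71 (SE 0.12, adjusted p = 0.333, and 0.0206 to 0.999 over the alternatives). The heat shock list differed in response by a median of 0.22 (camera adjusted p = 0.0165, and adjusted p = 0.629 with an estimated correlation, and 0.00341 to 0.331 over the alternatives).

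Other splits of the arrays were counted for each number of probe sets. The 6 arrays of the kainate effect in controls, of the kainate effect in mutants, and of genotype under saline or under kainate allow 10 splits each, too few for a share under 0.05. The real counts were 41, 37, 17 and 44, each in 1 of its 10 splits, and the highest counts of the others were 0, 0, 0 and 1. For the averaged genotype effect chance is unlikely, since the real count of 76 was reached in 1 of 100 relabellings of genotype within treatment and the highest other was 1. That share is the smallest these relabellings can give, and the probe sets counted are not independent of each other. With genotype swapped only between same-numbered arrays and the replicate block in the fit, its count of 124 was reached in 1 of 32 relabellings (highest other 0). For the interaction the real count was 0, which each of the 100 relabellings reaches by construction (highest other 1), so they say nothing about chance.

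The microglia and reactive glia lists were higher in the mutants at both treatments by camera, though under kainate reactive glia lost the call with an estimated correlation (adjusted p = 0.052). A lower share of neurons that only raised the markers of every other cell type alike is argued against by the arrays. The microglia score rose above the oligodendrocyte score by 0.823 between genotypes (exact permutation p = 0.005). That does not exclude a loss of neurons. Between same-numbered arrays the CA1 score was lower in mutants in 6 of 6 (-0.744 to -0.325), and the general neuron score was higher in 1 of 6. A replicate 1 shift shared by all groups cancels between genotypes by design, since each group holds 1 replicate 1 array. A difference present only in replicate 1, or only in the others, is argued against by the same-numbered comparisons. There the mutant array exceeded the control array in the microglia score by 0.654 to 0.84 in 6 of 6. A difference in sex between the pools is argued against by Xist, which ranged over 3.27 among control and 3.91 among mutant arrays, while the microglia score, after subtracting group means, ranged over at most 0.24 within a genotype, against 0.737 between genotypes. A genotype-linked change in the number or state of microglia and astrocytes may be the source, as a hypothesis found on these arrays. It was not itself tested, and neither was litter or strain background.

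Smaller kainate responses of Atf3, Gadd45b and Gpr19 in mutants were called only where the control kainate replicate 3 array was left out or weighted down. Compressed values on that array may hide the difference. Over the immediate early list its response had a slope of 0.906 (SE 0.0264) on the mean of the other control kainate arrays. The slopes of those arrays were 1.04 (SE 0.0223) and 1.04 (SE 0.0186). Each of these was taken on a mean that includes the replicate 3 array. A low replicate 3 array raises them, so they are no separate reference. The SEs treat genes as replicates, which they are not. Chance is not excluded, and the relabellings could not settle it. Without that array 20 of 100 relabellings of genotype gave as many as the real 5 calls. Each of these kept the real kainate labels or put both kainate replicate 1 arrays together as control. The highest others, 945 and 825, point to a structure of the samples. Both put the saline replicate 1 arrays together as mutant and the kainate ones as control. Keeping that block in the relabellings and the fit, 12 of 72 gave as many as the real 6 (highest other 255). Each of these 12 kept the real kainate labels. Swapping saline labels hardly changed whether the count was reached, so the share could not fall under 0.05. The 21 other responders had a median ratio of mutant to control response of 0.989 (quartiles 0.873 and 1.11), so they were not lowered alike. The ratio was 0.61 for Atf3, 0.371 for Gadd45b and 0.0804 for Gpr19. These genes were picked from these arrays for smaller responses, so their contrast with the rest is no test. The ratio also takes in the saline level, and the immediate early score differed by -0.23 between genotypes under kainate (exact permutation p = 0.2). Weaker seizures or a lower dose effect in mutants are thus not excluded, and an effect of the lost factors stays open.

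H1f2, Rmdn3, Stk16, Coq7 and Imp3 belong to none of the glial lists and differed between genotypes averaged over treatments, but of these H1f2 and Rmdn3 passed at both treatments, while Stk16 (adjusted p = 0.125) and Coq7 (0.137) did not under saline and Imp3 (0.077) not under kainate. Chromosome segments of another strain around the targeted loci are argued against for H1f2, Rmdn3, Coq7 and Imp3, of which 0 of 4 lie on chromosome 1 of Creb1 or chromosome 18 of Crem. For Stk16 a linked segment and an effect of the lost factors cannot be told apart, since it lies 82 protein-coding genes from Creb1 on chromosome 1 and no genotypes are at hand. Within 200 genes of either locus 2 called genes were found, Stk16 and Cd14, against 1.85 expected (exact one-sided hypergeometric p = 0.558).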

How the results depend on the processing

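The replicate 1 batch block, the restriction to replicates 2 and 3 and the block without the control kainate replicate 3 array were chosen after seeing the data, and the other alternatives before. Of 3218 gene values under alternatives 2710 kept direction and call, 459 lost the call, 12 gained it and 37 changed sign. Among the 3218 were 686 of Creb1 and Crem, which, like the interaction genes, had no call to lose. Of the called named genes, 14 of 20 for kainate in controls and 12 of 19 in mutants held in every alternative. For genotype 1 of 13 held under saline, 1 of 25 under kainate and 16 of 25 averaged. All 37 values that changed sign belonged to Creb1 or Crem, were uncalled, and lay between -0.0516 and 0.0411. Of 880 list values 790 kept the call and 90 lost it. Lists were not run with only the arrays compared or with the fold requirement. The filter on level gave values for 107 of 137 gene results, and none for the Creb1 probe sets, the dimmer Crem and the middle Atf3 probe set, Ppp1r15a, Cd52 and Lefty1. Only the arrays compared gave 97, since the interaction and averaged effect need all arrays. Replicate 1 alone holds 1 array per group and gives no test. The cause of the changes below was not tested, except that fewer arrays or genes were fitted where the setting says so.

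The replicate block gave 30 probe sets for genotype under saline, 67 under kainate and 124 averaged. It ended the calls of Pkia for kainate in controls, Tef and Cdkn2d in mutants, Imp3 under saline and D430019H16Rik under kainate, and changed no other call of a named gene or called list. Over all groups 8 of 12 arrays correlated best with their own number. Centring on medians gave 20 for genotype under kainate. Only the arrays compared gave 22 for kainate in controls and 5 for genotype under kainate. Gene averages gave 11 for genotype under saline and 29 under kainate. Array weights, which gave the control kainate replicate 3 array a weight of 0.0321, gave 380 for kainate in controls, 1619 in mutants, 8 for the interaction, 680 and 99 for genotype under saline and kainate, and 478 averaged. They moved the correlation over immediate early genes to 0.926 and the slope to 0.885. The replicate 1 batch block gave 64 for kainate in mutants, 38 and 77 for genotype under saline and kainate, and 140 averaged. Replicates 2 and 3 gave 146 and 94 for kainate in controls and mutants, 2 and 10 for genotype under saline and kainate, and 47 averaged. The block without the control kainate replicate 3 array gave 79, 173, 6, 70, 73 and 255 for the 6 contrasts in that order.

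With each array left out the counts ran from 27 to 56 for kainate in controls, 26 to 51 in mutants, 0 to 5 for the interaction, 8 to 20 and 12 to 38 for genotype under saline and kainate, and 41 to 103 averaged. The correlation over all probe sets ran from 0.52 to 0.833, that over immediate early genes from 0.935 to 0.95, and the slope from 0.895 to 0.92.

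Sign changes of Creb1 with quantile normalisation were -0.0104 for kainate in controls, 0.00726 in mutants and 0.00015 for the interaction. Centring on medians gave 0.028 for Crem and 0.0158, 0.0265 and 0.016 for Creb1 in mutants. Array weights gave -0.00578 for Crem and -0.035 for Creb1 in controls, 0.0164 and 0.00882 for Crem and 0.00606 and 0.0176 for Creb1 in mutants, and 0.0221 for Crem and 0.0411 and 0.0153 for Creb1 in the interaction. Replicates 2 and 3 gave 0.00935 for Crem and 0.0139 and 0.0208 for Creb1 in mutants. The block without the control kainate replicate 3 array gave -0.0516, -0.0324 and -0.0328 for Creb1 in controls and 0.0197, 0.0112 and 0.00108 in the interaction.

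With each array left out Creb1 ran from -0.0440 to 0.148, -0.0238 to 0.272 and -0.0200 to 0.215 for its 3 probe sets for kainate in controls, each lowest without control kainate replicate 3. In mutants it ran from -0.0545 to 0.00165, -0.0373 to 0.0105 and -0.0566 to 0.00159, and the dimmer Crem probe set from -0.0421 to 0.0192, each highest without mutant saline replicate 1. In the interaction 2 Creb1 probe sets ran from -0.180 to 0.0121 and -0.293 to 0.00263. For genotype under saline 2 ran from -0.0582 to 0.0141 and -0.0629 to 0.0316, each highest without control saline replicate 1.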

Other observations

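The tests of the lists in this part were chosen after the data had been seen, so their results are not independent of it. Lysosomal genes were higher in the mutants: of 24, Man2b1, Ctss, Ctsd and Hexa (0.36, SE 0.06) rose averaged over treatments, 0 fell and 20 did not pass (median 0.31, camera adjusted p = 7.63e-18, and adjusted p = 0.000812 with an estimated correlation). Of these 24 Ctss is also a microglial marker, Ctss and Ctsd are reactive glia genes, and Npc1 and Npc2 belong to the cholesterol efflux list. The microglia list rose with them (median 0.82), so the lists are not separate evidence. Of 13 genes of antigen processing and presentation Psmb8 and Cd74 rose and 11 did not pass (median 0.18, adjusted p = 3.75e-06, and adjusted p = 0.0443 with an estimated correlation). Under kainate the call of this list (adjusted p = 0.000115) was lost with an estimated correlation (adjusted p = 0.093). The list shares B2m, H2-D1 and H2-K1 with the reactive glia list. Interferon response genes were not called by camera in the averaged contrast (12 genes, median 0.00, adjusted p = 0.648). Camera called them as higher under saline (adjusted p = 0.0163) and for kainate in controls (adjusted p = 0.0477). With an estimated correlation both calls were lost (adjusted p = 0.439 and 0.702). Growth arrest and apoptosis genes, which share Btg2, Gadd45b and Gadd45g with the immediate early list, responded to kainate: of 12, Btg2, Gadd45g, Gadd45b and Ppp1r15a rose in controls (median 0.31, adjusted p = 2.51e-10, and adjusted p = 0.0125 with an estimated correlation), and Btg2 and Gadd45g in mutants (median 0.37, adjusted p = 7.59e-13, and adjusted p = 0.00607 with an estimated correlation). In the interaction lysosomal genes (median 0.13, adjusted p = 0.0129) had an adjusted p = 0.286 with an estimated correlation, interferon genes (-0.16, adjusted p = 0.0204) had an adjusted p = 0.685 with an estimated correlation, and growth arrest genes (-0.13, adjusted p = 0.0367) had an adjusted p = 0.495 with an estimated correlation.

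Camera did not call receptor and channel genes between genotypes, averaged over treatments: glutamate receptors (12 genes, median -0.09, adjusted p = 0.148), GABA-A receptors (8 genes, -0.08, adjusted p = 0.648) and voltage-gated potassium channels (11 genes, -0.07, adjusted p = 0.386). Fry called the glutamate receptors as lower (adjusted p = 0.00199), and also under kainate (adjusted p = 0.00388), with 11 of 12 negative in each. NF-kappa B feedback genes (10 genes, -0.07, adjusted p = 0.744) and 20 histone genes (-0.07, adjusted p = 0.69) were not called by camera either, and for both the median was negative while the mean was positive. Fry's mixed test called the histones (adjusted p = 7.88e-09), among which H1f2 rose, and probe sets shared by several histone genes were also higher in mutants, by 1.15 (SE 0.13) for the H3 cluster and 0.93 (SE 0.08) for the H2B cluster. A probe set shared by the complement genes C4a and C4b was higher by 2.29 (SE 0.21, adjusted p = 0.000797). Bok, a BCL2 relative in the CA3 and CA2 list, rose by 0.69 (SE 0.11). The opioid precursor Penk stood at -0.75 (SE 0.14, adjusted p = 0.0532).

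Xist, transcribed from the inactive X chromosome, was 5.98 to 7.59 in the replicate 2 pools of all 4 groups, 6.56 in mutant kainate replicate 3, 5.01 in mutant saline replicate 3 and 3.23 to 3.96 in the other 6 pools. Its averaged genotype difference was 1.23 (adjusted p = 0.63). In each same-numbered comparison the mutant pool lay above the control pool. The gap was narrow for kainate replicate 1 (3.68 against 3.64) and wide for kainate replicate 3 (6.56 against 3.92). A balance of the sexes between genotypes was therefore not shown, and sex was weighed for the microglia score alone. Of the 66 control probe sets, 0 passed in limma in any of the 6 contrasts, with 0 to 12 at unadjusted p under 0.05.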
